A study of Escherichia coli with 8 samples.

How the data were processed

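RNA from 8 samples of Escherichia coli was studied, 2 per group, before and at 5, 10 and 15 min after induction of plasmid-borne rpoH. Per the labels, total RNA was reverse-transcribed, labelled and hybridized to Affymetrix E. coli antisense genome arrays. The deposited values are the authors' processed probe set intensity on a linear scale, with 1 column per sample. The summarization of probes, the background step and the scaling are not given in the sources used here. From the values alone, the mean of each array after trimming 2% at either end is close to 1000 (998.9 to 1000.9), so arrays appear to have been scaled to a common trimmed mean. The scale is linear and, with 1 colour, the ratio direction needs no choice. The median of all values per array lay between 286 and 343. There were 8 zeros among the values, and 0 columns were left unused.

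The arrays hold 7312 probe sets: 4345 for genes, 2886 for intergenic regions, 22 array controls and 59 for phage and plasmid sequences. Genes were named through the locus tag in the probe set name with a RefSeq gene table of assembly ASM584v2, used for names only. Of the gene probe sets 4183 matched, and 162 keep the array's own name. The platform's annotation gives 1 gene symbol for 3804 probe sets, several for 594 and none for 2914. Each gene has 1 probe set. No gene coordinates are printed. Intergenic probe sets are named by the coordinates in their names, whose genome build is not given in the sources used here.

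A pseudocount of 26.3 intensity units, 5% of the median gene value, was added before log2 was taken, and each array was centred on its median over gene probe sets. The dimmest 20% of genes by mean were left out, leaving 3476. Fold changes are on the log2(value + pseudocount) scale, which understates the change of dim genes. All 8 samples were fitted in 1 limma model (limma 3.58.1, R 4.3.3) of 4 groups without a block, with lmFit and eBayes with an intensity trend. Each time was tested against the control and against the other times, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 4 residual and 5.96 prior degrees of freedom. All p-values given as adjusted come from limma, and SE denotes its moderated standard error. Replicate arrays all differed from each other: the median absolute log2 difference within a group was 0.26 for the controls, 0.48 at 5 min, 0.32 at 10 min and 0.28 at 15 min.

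The 18 gene lists cover sigma32 chaperones, proteases and other reported targets, sigmaE, Cpx, phage shock, RpoS, SOS, oxidative stress, mar and efflux, cold shock, ribosomal proteins, flagella and chemotaxis, glycolysis, TCA cycle, ATP synthase, nucleotide synthesis and amino acid synthesis. They were tested with camera at a preset correlation of 0.01, adjusted over 54 tests for the 3 comparisons with the control. The union of the 3 sigma32 lists was adjusted over 3 tests. Both were repeated with an estimated correlation and with fry. No list call holds with an estimated correlation. The lists, their tests against the control, the gene tests against the control and between 5 and 15 min, the F test, the alternatives and the rule for naming genes were set before the data were examined. The list tests between 15 and 5 min, the gene tests of 10 min against 5 min and of 15 min against 10 min, and the overlap of calls were chosen after that. The rule names rpoH, every sigma32 chaperone and protease gene, up to 10 genes with the largest rise and 10 with the largest fall per comparison among called genes whose samples do not overlap between groups, up to 2 members at either end of every other list, and up to 5 intergenic probe sets. Other members of a list are named where 5 or fewer were called, chosen after their values were seen.

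The model was tested on simulated data for 5 min against control, with 3476 genes of which 200 were changed, over 20 runs. It recovered 23.8% of 2-fold and 88.5% of 4-fold changes, with 4.90% false calls among calls. Camera called 20 of 20 shifted lists of 40 genes and 0 unshifted lists. The simulated genes varied independently of each other, so this does not test camera on lists of correlated genes. They also had the same spread in every group. In the data the 5 min replicates differed more than the controls (median absolute log2 difference 0.48 against 0.26). The simulated share of false calls therefore does not give that share in the data. In the data the estimated correlation within the sigma32 union was 0.81. As a level for background, the 95th percentile of 56 phage and plasmid probe sets, which leaves out the bla and tet plasmid probe sets, was used. This level was 397 and 449 on the controls and 566 to 955 on the induced arrays. It lay above the median gene on every induced array and below it on both controls. Induced samples therefore lay under it more readily than controls.

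Alternatives were the values without centring, quantile normalization, pseudocounts of 1% and 25%, no filter or a 40% filter on dim genes, no intensity trend, a replicate block, leaving out each replicate, a 2-fold minimum, an adjusted p under 0.01, and the list tests named above. Centring on protein-coding genes was added after seeing the data.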

Results

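Transcript levels were measured in Escherichia coli cultures before and after induction of a plasmid-borne rpoH gene, which encodes sigma32, the sigma factor of the heat shock response. Anhydrotetracycline was the inducer, and cells were taken in mid-log phase at an optical density of 0.2. The 8 samples form 4 groups of 2: a control taken before induction, and samples taken 5, 10 and 15 min after it. In each group, replicate 1 belongs to a first set of samples and replicate 2 to an additional set. The labels describe the additional induced samples as coming from a separate culture, and do not say this of the additional control. P-values measure only the spread between these samples, part of which may be technical. The summed probe set intensity per array lay between 10984876 and 17290275, and the number of arrays limits the precision. The sum differed with the groups, at 10984876 and 12532266 in the controls and 16516074 and 17290275 at 15 min. The 10 brightest probe sets held 4.0% and 6.1% of it in the controls and 9.6% and 9.7% at 15 min. Bright signals thus held a larger share at 15 min than in the controls. No uninduced sample later than the control was analysed here, so induction, the inducer itself and time in culture change together in each comparison with the control.

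The rpoH probe set (b3461) was bright in every induced sample. Its intensity was 1094 ± 34.5 (SD, n = 2) in the control, 72635 ± 27728 at 5 min, 98897 ± 9529 at 10 min and 137907 ± 11619 at 15 min, also n = 2 each. On the log2 scale the rise was 5.93 ± 0.37 (SE) at 5 min, 6.39 at 10 min and 7.00 at 15 min, with adjusted p of 6.4e-05, 3.1e-05 and 1.3e-05. These correspond to 60.9-fold, 83.6-fold and 128.1-fold. The probe set reads chromosomal and plasmid transcripts together.

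**Figure D1:**
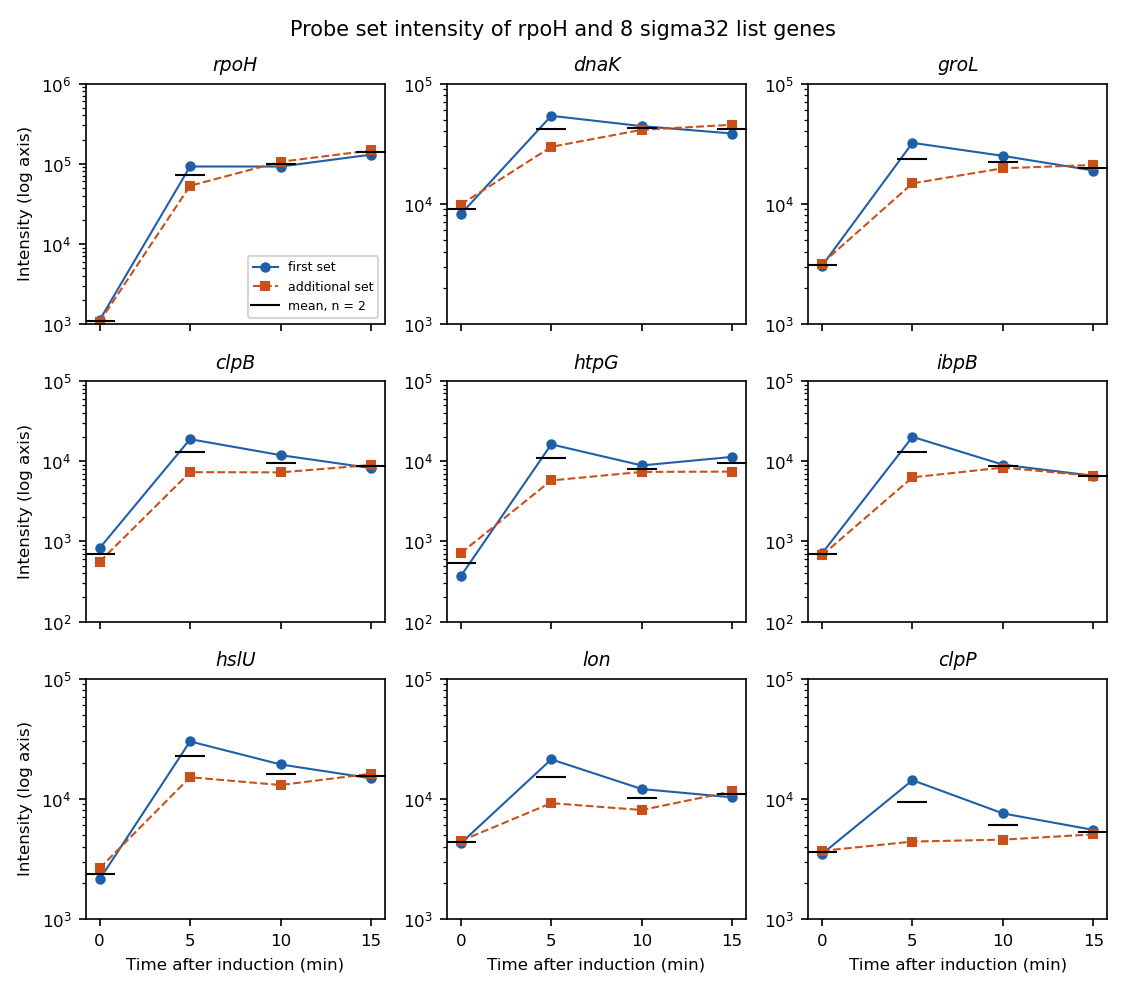
Intensity (log axis) of rpoH and 8 genes of the sigma32 lists against time after induction in min, for the first set (circles), the additional set (squares) and their mean (bars, n = 2). At 5 min the first set lies above the additional set for each gene shown, as for clpB with 18821 against 7302.

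The labels give the genes under sigma32 control as the subject of the study, and the comparison at 5 min asks which transcripts differed first. Heat shock chaperone and protease genes and other reported sigma32 targets made up 28 of the 81 rises. All 11 genes of the chaperone list fixed beforehand, which includes hslR, rose. They were led by htpG (b0473), the Hsp90 homolog, with a log2 change of 4.13 ± 0.47 (SE, adjusted p = 0.0024), and clpB (b2592), a disaggregase, with 4.02 ± 0.41 (16.3-fold, adjusted p = 0.0024). The small heat shock protein genes ibpB and ibpA rose by 3.94 and 3.57, the nucleotide exchange factor gene grpE by 3.39, and hslR by 3.06. The Hsp70 gene dnaK rose by 2.11, its partner dnaJ by 1.46, the chaperonin genes groL and groS by 2.76 and 1.91, and hslO, the gene of the redox-regulated chaperone Hsp33, by 2.16. The list median was 3.06, with an SD over members of 0.94.

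Of the 8 protease genes, 5 rose at 5 min. The subunit genes of the HslUV protease rose by 3.11 for hslU and 2.56 for hslV, the oligopeptidase gene prlC by 2.62, the membrane protease gene htpX by 2.04 and lon by 1.64. The other members did not pass over all genes: ftsH, an essential membrane protease gene, had a log2 change of 1.66 (adjusted p = 0.071), clpX 1.27 (0.15) and clpP 1.10 (0.18). Among 20 further genes reported as sigma32 targets, 12 rose, with ldhA, the gene of lactate dehydrogenase, at 3.21 and ycjF at 3.19. The ycjF control values lay within the range of phage and plasmid probe sets, so its fold is open upward. The gene of the housekeeping sigma factor, rpoD, had 0.29 ± 0.51 (adjusted p = 0.78). It was 1.42 in the first set and -0.83 in the additional set.

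Over the union of these lists, 28 of 39 genes rose at 5 min and 0 fell, and 37 rose when adjusted over the list alone. Adjusted over each list alone, 11 chaperone, 8 protease and 18 other genes rose. The union median was 2.11 (SD over members 0.94), higher in both sets for 38 of 39 genes, with 2.72 in the first set and 1.36 in the additional set. The camera test with a preset correlation gave an adjusted p of 1.3e-37. This call was lost with the adjusted p = 0.091 obtained with an estimated correlation, while fry gave an adjusted p of 0.012. Taken singly, the chaperone, protease and other target lists had camera adjusted p of 1.9e-17, 7.4e-09 and 5.5e-18 at 5 min, each with an adjusted p = 0.395 with an estimated correlation. By fry only the chaperone list passed, with 0.025 against 0.060 and 0.054.

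Genes outside these lists also rose at 5 min. They included bssS, a regulator of biofilm formation, with a log2 change of 3.64 ± 0.55 (adjusted p = 0.0089), and macB, a macrolide exporter subunit gene, with 3.12 ± 0.47 (adjusted p = 0.0090). Falls of the largest size included 3 insA genes of insertion sequence IS1, at -3.45 for insA5, -3.08 for insA1 and -2.66 for insA2. These probe sets share sequence between copies, so which copy changed is uncertain. The other falls of the largest size were in the histidine synthesis genes hisD at -2.73 and hisH at -2.47, the isoaspartyl peptidase gene iaaA at -2.67, the flagellar hook gene flgE at -2.31, the iron-sulfur cluster assembly gene sufD at -2.29, gluQ at -2.29 and nmpC at -2.25. The hisH and sufD calls lay at the threshold, with an adjusted p of 0.050 each. Both 5 min samples lay under the 95th percentile of phage and plasmid probe sets for iaaA, sufD and gluQ, and 1 of 2 did for hisD, hisH and the insA genes, so the sizes of these falls are uncertain. For the rises of htpG, bssS and prlC 1 of 2 controls lay under that level, so their sizes are uncertain at each time.

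Part of the amino acid synthesis and motility genes fell at 5 min. In the amino acid list 12 of 39 genes fell and 0 rose, 31 fell adjusted over the list alone, and the median was -1.01 (camera adjusted p = 4.5e-16, adjusted p = 0.395 with an estimated correlation, fry 0.025). In the flagella and chemotaxis list 6 of 18 fell, 7 adjusted over the list alone, led by flgE and flgD (-1.68), with a median of -0.64 (camera adjusted p = 7.7e-06, adjusted p = 0.395 with an estimated correlation, fry 0.038).

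Among 3476 genes tested at 5 min, 81 were higher and 96 lower, 177 in all, and 822 had an unadjusted p under 0.05. The count was 16 without control replicate 1, 20 without control replicate 2, 80 without 5 min replicate 1, 776 without 5 min replicate 2, 111 without either 10 min replicate, 75 without 15 min replicate 1 and 73 without 15 min replicate 2. It was 89 without an intensity trend in the variance and 38 at an adjusted p under 0.01, and quantile normalization moved the higher share from 45.8% to 58.3%. That share was 81.3% without control replicate 1 and 90.0% without control replicate 2.

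At 10 min most genes of the chaperone list were again higher than in the control. Of its 11 genes 9 rose, and all 11 did so adjusted over the list alone. The largest were htpG at 3.83 ± 0.47 (SE, n = 2 per group, adjusted p = 0.0031), clpB at 3.65, ibpB at 3.53, grpE at 3.46 and ibpA at 3.19. The chaperonin gene groL rose by 2.75, hslR by 2.63, groS by 2.21 and dnaK by 2.17. The exceptions were hslO, with 1.66 (adjusted p = 0.051), and dnaJ, with 1.02 (adjusted p = 0.051). Of the proteases, hslU rose by 2.65, prlC by 2.28 and hslV by 2.06. The remaining 5 did not pass: ftsH had 1.60, htpX 1.30, clpX 1.23, lon 1.10 and clpP 0.63. Adjusted over the list alone, 7 of 8 proteases rose. Among the further reported targets 12 of 20 rose, 19 adjusted over the list alone, with ldhA at 2.96 and ycjF at 2.91, while rpoD had -0.10, a sign that turned to 0.11 under quantile normalization.

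The union of the sigma32 lists had 24 of 39 genes higher and 0 lower at 10 min, 37 higher adjusted over the list alone. Its median was 1.66, with 1.98 in the first set and 1.41 in the additional set. Camera gave an adjusted p of 7.4e-27, the adjusted p was 0.091 with an estimated correlation, and fry gave 0.012. Outside the lists, ygcU rose by 2.99, from control values within the range of phage and plasmid probe sets, and bssS by 2.97.

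The falls at 10 min took in 25 of 39 amino acid synthesis genes, 34 adjusted over the list alone, with 0 rises and a median of -1.16. The hisH change was -3.59 ± 0.62 (adjusted p = 0.012) and that of hisD -3.53 ± 0.48 (adjusted p = 0.0053). Camera gave an adjusted p of 4.5e-16, against an adjusted p = 0.395 with an estimated correlation and 0.025 by fry. In the flagella list 8 of 18 genes fell, 9 adjusted over the list alone, with flgE at -2.75 and flgD at -2.15 (list median -0.62, camera adjusted p = 9.5e-05, adjusted p = 0.395 with an estimated correlation, fry 0.031). The flgB change of -4.04 rested mainly on the additional set, at -6.63 against -1.46 in the first set. The flagellar P-ring gene flgI, in no list, fell by 3.49. Other large falls were insA5 at -4.29, insA1 at -3.69, insA2 at -3.13, iaaA at -3.05, arnB, a lipid A modification gene, at -2.90 and sufD at -2.77. Both 10 min samples of hisD, hisH, iaaA, arnB, flgI, sufD and cpxA, and 1 of 2 for flgB, ppiA, pgi and the insA genes, lay under the phage and plasmid level, so the sizes of these changes are uncertain.

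Some envelope genes under sigmaE fell at 10 min, 4 of 15, 7 adjusted over the list alone: bamA (-1.82), encoding the core of the outer membrane assembly complex, bamD (-1.02) of the same complex, and the periplasmic chaperone genes fkpA (-1.56) and skp (-1.33). The median was -0.68 (camera adjusted p = 0.0035, adjusted p = 0.395 with an estimated correlation, fry 0.026). The periplasmic protease gene degP, in the same list, had 0.97 (adjusted p = 0.14). The glycolysis genes eno and pgi fell by 1.68 and 1.51, the aconitase gene acnB rose by 1.15, and the purine synthesis genes purF, guaA and purH fell by 1.02, 0.94 and 0.94.

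In all, 109 genes were higher and 262 lower at 10 min, 371 of 3476, with 1026 at an unadjusted p under 0.05. Changes are relative to the median of each array over gene probe sets, and the median change of all tested genes was -0.11. The count was 20 without control replicate 1, 22 without control replicate 2, 54 without 10 min replicate 1, 151 without 10 min replicate 2, 139 and 136 without 15 min replicates 1 and 2, and 761 and 776 without 5 min replicates 1 and 2. It was 193 without an intensity trend and 35 at an adjusted p under 0.01, and quantile normalization moved the higher share from 29.4% to 45.8%. Without control replicate 1 or 2 most of the remaining calls were rises, as at 5 and 15 min, so the excess of falls was not seen there. Too few calls remained for their share to show whether this excess depends on the controls. The median change of all tested genes was then -0.12 and -0.08.

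At 15 min all 11 genes of the chaperone list were higher than in the control, also adjusted over the list alone. The htpG rise was 4.15 ± 0.47 (SE, n = 2 per group, adjusted p = 0.0046, its size uncertain as 1 of 2 controls lay under the phage and plasmid level) and that of clpB 3.67 ± 0.41 (adjusted p = 0.0046). The grpE rise was 3.41, ibpB 3.26, ibpA 3.08, groL 2.73, hslR 2.59, dnaK 2.27, groS 2.25, hslO 2.08 and dnaJ 1.16. Of the proteases hslU rose by 2.75, hslV by 2.21 and prlC by 1.95, and 6 of 8 rose adjusted over the list alone. The others had 1.65 for ftsH (adjusted p = 0.055), 1.39 for htpX, 1.37 for lon (adjusted p = 0.051), 0.89 for clpX and 0.62 for clpP. Among the further reported targets 11 of 20 rose, 18 adjusted over the list alone. They included ldhA at 2.89, ycjF at 2.61 and gapA, the glyceraldehyde-3-phosphate dehydrogenase gene, at 1.57. The gapA values at 5 and 10 min were 0.96 and 1.38, neither past the threshold. The rpoD change was -0.17 (adjusted p = 0.85), and 0.09 without control replicate 2.

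The union had 25 of 39 genes higher and 0 lower at 15 min, 35 higher adjusted over the list alone. The median was 1.82, and the sets lay close together at 1.83 and 1.78. Camera gave an adjusted p of 5.6e-26, with an adjusted p = 0.091 with an estimated correlation and 0.012 by fry.

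**Figure D2:**
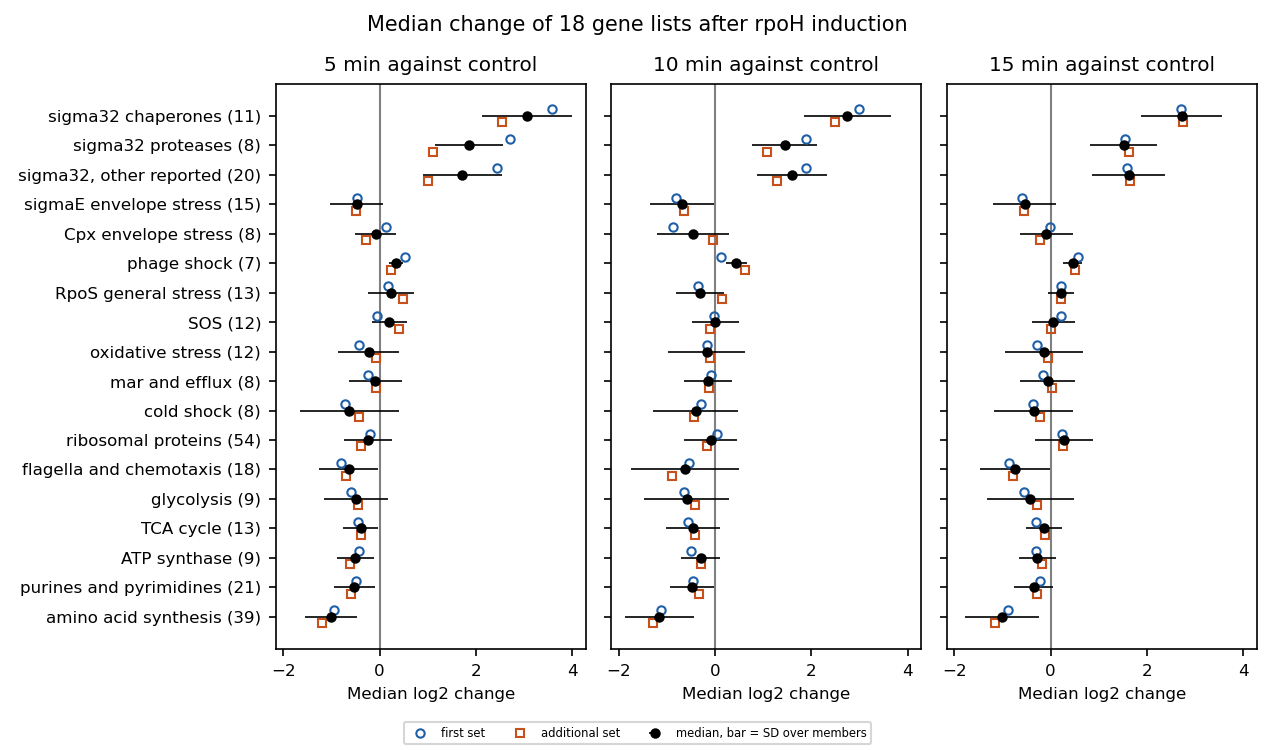
Median log2 change against control (x axis) of 18 gene lists (y axis, number of tested genes in brackets) at 5, 10 and 15 min, as black points with bars of 1 SD over members, beside the medians of each set of samples. The 3 sigma32 lists lie to the right at each time and amino acid synthesis lies furthest left, at -1.01, -1.16 and -1.01, while ribosomal proteins at 15 min (0.28) turn to -0.38 under quantile normalization.

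Transfer RNA genes joined the largest rises at 15 min: proK at 3.86 ± 1.01 (adjusted p = 0.043), leuU at 3.50 ± 0.72 and serT at 2.96 ± 0.40. The proK change was 5.54 in the first set and 2.19 in the additional set, and that of leuU 2.03 and 4.98. For proK and leuU 1 of 2 controls lay under the phage and plasmid level, so size and rank are uncertain. Of the amino acid synthesis genes 18 of 39 fell at 15 min, 28 adjusted over the list alone, with a median of -1.01. The hisH change was -3.92 and that of hisD -3.53 (camera adjusted p = 6.7e-15 for the list, adjusted p = 0.395 with an estimated correlation, fry 0.025). In the flagella list 7 of 18 genes fell, 9 adjusted over the list alone, with flgE at -2.33 and flgD at -1.80 (median -0.74, camera adjusted p = 4.0e-05, adjusted p = 0.395 with an estimated correlation, fry 0.038). Other large falls were insA5 at -3.85, insA1 at -3.33, insA2 at -2.77, the mannose transporter gene manZ at -2.95, iaaA at -2.94, the nitrogen regulator gene glnK at -2.66, flgI at -2.61 and the agmatinase gene speB at -2.52. Both 15 min samples of hisD, hisH, iaaA, manZ, glnK, flgI, pgi and the insA genes lay under the phage and plasmid level, so the sizes of these falls are uncertain.

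Of 54 ribosomal protein genes 4 rose at 15 min, also 4 adjusted over the list alone: rplT at 2.21, rpsT at 1.37, rpmF at 1.35 and rpmI at 1.34. The list median of 0.28 turned to -0.38 under quantile normalization (camera adjusted p = 0.0089, adjusted p = 0.805 with an estimated correlation). At 10 min rplC (-1.40) and rplW (-1.21) of this list fell, but 0 adjusted over the list alone, and camera's direction there was up although the median was -0.09. Of the sigmaE list bamA (-1.24) and fkpA (-1.14) fell at 15 min, 5 fell and 1 rose adjusted over the list alone, and degP had 1.33 (adjusted p = 0.063). The list's camera adjusted p was 0.036 there and 0.099 at 5 min, with an adjusted p = 0.395 and 0.456 with an estimated correlation.

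In all, 144 genes were higher and 175 lower at 15 min, 319 of 3476, with 986 at an unadjusted p under 0.05. The count was 13 without control replicate 1, 18 without control replicate 2, 1 without 15 min replicate 1, 2 without 15 min replicate 2, and 718 and 709 without 5 min replicates 1 and 2. It was 196 without an intensity trend and 53 at an adjusted p under 0.01, and the higher share of 45.1% was 53.8% under quantile normalization, 36.4% without centring, and 69.2% and 77.8% without control replicate 1 or 2.

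Other stress lists held few or no calls at any time. Of all 3476 genes tested, 177 were called at 5 min, 371 at 10 min and 319 at 15 min. Lists this short would hold few calls at that share too. Their low counts therefore do not show that these responses were absent. The SOS list (12 genes tested), the oxidative stress list (12), the RpoS general stress list (13) and the phage shock list (7) had 0 calls, over all genes or adjusted over the list alone. Examples are the recombinase gene recA with 0.77 at 5 min, the glutaredoxin gene grxA with 0.72 at 15 min, osmY with -0.40 at 15 min and pspC with 0.66 at 5 min and 0.68 at 15 min. Both 15 min samples of osmY lay under the phage and plasmid level, so the size of its change is uncertain. The filter on dim genes left out 4 of 17 RpoS genes and 1 of 13 SOS genes on the array. The phage shock list gave a camera adjusted p of 0.036 at 5 min and 0.040 at 15 min, each with an adjusted p = 0.395 with an estimated correlation, and 0.091 at 10 min. The lowest camera adjusted p was 0.12 for SOS, 0.54 for oxidative stress and 0.28 for RpoS. In the mar and efflux list acrA, an efflux pump subunit gene, fell at each time, by 1.40, 1.15 and 1.25. In the cold shock list infB, a translation initiation factor gene, fell at 5 min (-1.17) and 10 min (-1.02), while cspA had 0.74 at 10 min. In the Cpx list ppiA fell at 10 min (-1.55) and cpxA had -1.32 (adjusted p = 0.051). Adjusted over the list alone, 1 mar gene fell at each time, 4 cold shock genes fell and 1 rose at 5 min, 4 fell at 10 min, and 2 Cpx genes fell at 10 min. The lowest camera adjusted p was 0.684 for the mar list, 0.449 for cold shock and 0.544 for Cpx. Camera pointed up against a negative median for the Cpx list at 5 and 15 min (-0.08 and -0.09, the first 0.08 under quantile normalization) and the RpoS list at 10 min (-0.31).

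Of 9 glycolysis genes 1 fell at 5 min, 2 at 10 min and 2 at 15 min, when 1 also rose. The glycolysis gene eno fell by 1.43 at 5 min and 1.35 at 15 min, and pgi by 1.53 at 15 min. The ATP synthase gene atpG fell by 1.11 at 10 min, and purH fell by 1.07 at 5 min. The purine and pyrimidine list had a camera adjusted p of 0.0076 at 5 min, with an adjusted p = 0.415 with an estimated correlation, and 0.097 and 0.18 later. Adjusted over the list alone, 5 nucleotide synthesis genes fell at 5 min and 3 at 10 min. For glycolysis 2, 3 and 2 genes fell and 0, 1 and 1 rose at the 3 times. For ATP synthase 1 and 2 genes fell at 5 and 10 min, and for the TCA cycle 1 rose at 10 min. The lowest camera adjusted p was 0.056 for glycolysis, 0.17 for the TCA cycle and 0.058 for ATP synthase. With a replicate block camera gave an adjusted p of 0.039 for glycolysis at 10 min and 0.021 for ATP synthase at 5 min. With an estimated correlation and no block camera gave 0.395 and 0.696 there, so these calls depend on the setting.

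The comparison of 15 min with 5 min tested whether the early and late responses differed. By limma no gene passed, 0 of 3476, with 161 at an unadjusted p under 0.05, a smallest adjusted p of 0.99, and 5 calls without 5 min replicate 2. The rpoH log2 change between these times was 1.07 (adjusted p = 0.99), and -0.11 under quantile normalization. The 10 min samples differed from the 5 min samples, and the 15 min from the 10 min samples, in 0 genes each, with 140 and 149 at an unadjusted p under 0.05. List tests between these times were not planned. The sigma32 union median from 5 to 15 min was -0.30. It was -0.99 in the first set, with 0 of 39 genes positive, and 0.40 in the additional set, with 37 of 39 positive. Camera gave an adjusted p of 8.5e-05, and the adjusted p was 0.73 with an estimated correlation.

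Over all 3 times, an F test by limma called 140 genes. Genes higher at every time numbered 56 and genes lower at every time 73. All comparisons share the same control pair, so these overlaps are not independent. In 100 simulations without effect, with the controls shared, both overlaps were 0, but such data gave almost no calls at all (a mean of 0.24 higher at any time), so how much of the overlap comes from the controls was not tested. The any-time count was 1 without control replicate 1, 6 without control replicate 2, 561 and 738 without 5 min replicates 1 and 2, 84 without 10 min replicate 1, 28 and 24 without 15 min replicates 1 and 2, 50 without an intensity trend and 17 at an adjusted p under 0.01.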

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

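The explanation by culture speed and the comparison of shares in the first 5 min sample were chosen only after the results were seen, and the list tests between 15 and 5 min were not set beforehand.

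By camera with a preset correlation, 4 lists differed between 15 and 5 min. The sigma32 protease list had a median log2 change of -0.37 (adjusted p = 0.034), the other reported sigma32 targets -0.30 (0.0073), ribosomal proteins 0.49 (1.5e-13) and nucleotide synthesis 0.24 (0.038). Each had an adjusted p = 0.851 with an estimated correlation. The ribosomal change was 0.04 under quantile normalization.

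The sigma32 lists together changed by -0.99 between 5 and 15 min in the first set and by 0.40 in the additional set. This difference was not tested, since each set has 1 sample per time. A wider signal range on the first 5 min array would have removed the fall in the first set. After each array was rescaled, the change there was still -1.04 ± 0.07 (bootstrap SE over genes), while the additional set moved to 0.10 ± 0.04. These SEs come from resampling genes and leave out the spread between samples. Uninduced RNA in the additional 5 min sample stays open: this array correlated more with the controls (r = 0.925 and 0.923 across genes) than with the first 5 min array (0.900), but most with the additional 10 and 15 min arrays (0.931 and 0.938). Genes that rose and fell at 10 min had reached shares of 0.55 and 0.76 of their change there, a difference of -0.20, which had been set beforehand as evidence against it, but in the first 5 min sample the shares were 1.33 and 0.98, so risen and fallen genes need not move in step. The reading was therefore changed to open after the result was seen. A different speed of the response in the separate cultures cannot be told apart from it with 1 sample per time.

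Intergenic probe sets, which the comparisons above leave out, held rises against the control: 45 of 2309 at 5 min, 41 at 10 min and 57 at 15 min. Falls numbered 24, 77 and 38. Among the rises was the reverse-strand probe set at 3597347 to 3597559, with log2 changes of 4.67, 4.88 and 4.98 (adjusted p of 4.0e-04, 5.3e-04 and 4.4e-04). Its control mean of 105.6 lay under the 95th percentile of phage and plasmid probe sets, so its fold is open upward.

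The values of the plasmid marker probe set bla were higher in both induced samples than in both controls at 10 and 15 min. The bla mean was 37685 in the control, 65797 at 10 min and 93951 at 15 min. The tet mean was 129.3 in the control, 335 at 5 min, 414.4 at 10 min and 260.9 at 15 min. Every tet value lay under the 95th percentile of phage and plasmid probe sets on its array, so no tet signal is claimed. Neither was tested.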

How the results depend on the processing

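Centring on protein-coding genes was chosen after seeing the data. The sigma32 medians of 2.11, 1.66 and 1.82 kept their direction under every alternative run. Their call was kept wherever camera ran with the preset correlation of 0.01. Those runs say little about the call, since the estimated correlation was 0.81. That correlation is taken from the residuals of all 4 groups together, so it is the same at each time and does not separate the times. The set medians differed most at 5 min (2.72 and 1.36) and least at 15 min (1.83 and 1.78). Camera with an estimated correlation gave an adjusted p of 0.091 at each time, and fry gave 0.012. Over alternatives that leave out a replicate the medians ranged from 1.44 to 2.62 at 5 min, 1.51 to 1.87 at 10 min and 1.67 to 1.94 at 15 min. Counts depended on single arrays: 16 (without control replicate 1) to 776 (without 5 min replicate 2) at 5 min, 20 to 776 (the same arrays) at 10 min, 1 (without 15 min replicate 1) to 718 (without 5 min replicate 1) at 15 min, 0 to 5 between 5 and 15 min, and 1 to 738 at any time. A lone sample is there assumed to vary like the other groups. Without an intensity trend counts were 89, 193, 196 and 50 (any time), and at an adjusted p under 0.01 they were 38, 35, 53 and 17. The replicate block gave 310 at 5 min, 553 at 10 min, 466 at 15 min and 272 at any time, with every main call at the 3 times shared. Deviations of same-numbered samples correlated from -0.07 to 0.20 across genes, under 0.1 for 3 of 6 pairs of groups, so the block was kept as an alternative. Other settings stayed within 1.5 times. Leaving out either 5 min array kept the log2 changes at 10 and 15 min, with sigma32 medians of 1.66 and 1.82. Those counts therefore moved through the shared estimate of the spread, and the 5 min pair differed most (0.48). The cause of the other moves was not tested. Of 168 named results, 102 and 100 lost their call without control replicate 1 or 2, 75 and 74 without 15 min replicate 1 or 2, 45 and 31 without 10 min replicate 1 or 2, 34 without a trend and 19 under quantile normalization. Reversals were rpoH from 5 to 15 min (-0.11, quantile normalization) and rpoD: -0.57 at 5 min without 5 min replicate 1 (1.16 without replicate 2), 0.11 at 10 min under quantile normalization, 0.16 without control replicate 2, 0.37 without 10 min replicate 2, and 0.0901 at 15 min without control replicate 2 (-0.43 without control replicate 1). Without a filter on dim genes 12 named results lost their call, while 9 gained one under quantile normalization and 7 with the replicate block. Averaging the probe sets of a gene was not run, since each gene has 1. Signal over background limits the rises of ycjF, ygcU, proK, leuU, htpG, bssS and prlC and the falls named as uncertain in size, among them hisD, hisH, iaaA and manZ.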

Other observations

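The grouping by RNA type and the question of time in culture were chosen only after the results were seen.

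Of 79 transfer RNA genes tested, 3 rose at 5 min, 23 at 10 min and 46 at 15 min, and 0 fell, with medians of 0.77, 1.20 and 1.66. In the first set the medians were 1.44, 1.24 and 1.75, and in the additional set 0.18, 1.11 and 1.47, so the lower value at 5 min rests on the additional sample. From 5 to 15 min the median change was 0.84 (0.42 under quantile normalization), with p = 0.058 with an estimated correlation and 0 genes called. Camera gave p = 3.8e-16, 1.1e-23 and 1.3e-33 at the 3 times, 0.13, 0.079 and 0.047 with an estimated correlation, and 0.058, 0.017 and 0.0054 by fry, none adjusted over lists. Of 5 small RNA genes 2 rose at 5 min (spf at 2.41 and ssrS at 1.90), 3 at 10 min and 4 at 15 min. Those at 15 min were spf at 2.60, ssrS, the 6S RNA gene, at 2.35, ffs, the signal recognition particle RNA gene, at 2.14 and rnpB, the ribonuclease P RNA gene, at 1.80. The small RNA median at 5 min was 2.02 in the first set and 0.35 in the additional set. None of 18 ribosomal RNA probe sets was called (0), with medians of 0.32, 0.98 and 1.63 that became -0.02, 0.06 and 0.12 under quantile normalization. At 5 min their median was 1.69 in the first set and -0.91 in the additional set. Many of the transfer and ribosomal RNA probe sets share sequence between copies, so single genes are uncertain. The 79 transfer RNA probe sets are therefore not 79 independent measures, which limits the counts and the camera p with a preset correlation.

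Within the amino acid list 4 of 4 leu, 2 of 3 thr, 6 of 8 his, 4 of 5 trp, 3 of 5 ilv, 5 of 9 arg and 1 of 5 met genes fell at 10 min, and 4, 2, 5, 1, 3, 3 and 0 at 15 min. Differences between these families were not tested. The medians at 15 min were -1.82 for 4 leu genes, -1.72 for 3 thr, -1.10 for 8 his, -0.96 for 5 trp, -0.87 for 5 ilv, -0.71 for 9 arg and -0.69 for 5 met genes, and 0 genes of these families rose at any time. Most called genes lay in no list: 52, 83 and 114 of the higher and 74, 214 and 145 of the lower genes at 5, 10 and 15 min. The largest of the 18 lists holds 54 of the 3476 tested genes, so most genes, called or not, lie in no list. These counts therefore do not place the response outside the lists.

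The transfer RNA rise may be a response of the cells, as a hypothesis. The array scaling or a bend in bright signals would have moved protein-coding genes of like brightness as much, but the median lay 1.50 above that of the matched lists and above all 10000 of them. Of the 79 genes, 67 lay within 0.25 of their matches in brightness, with a median of 1.69, and 12 were brighter. Added background would have raised phage and plasmid probe sets too. The transfer RNA gain, however, was 15984 ± 2494 intensity units (bootstrap SE over genes, not samples) against a 95th percentile of 460 for those. The SE and the matched lists treat the 79 probe sets as independent, although many share sequence between copies. Time in culture without induction cannot be told apart from induction, since 0 uninduced samples are later than the control.

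The fall of amino acid synthesis genes may likewise be a response of the cells, as a hypothesis. Its median at 15 min lay at -0.79 relative to lists matched on brightness and below all 10000 of them, which argues against the array scaling. A fall of the his and leu operons alone would have left the other members near 0. The 27 others, however, had a median of -0.88 ± 0.11 (bootstrap SE over genes, not samples). Time in culture cannot be told apart from induction here either, with 0 later uninduced samples.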
